A study of Homo sapiens with 4 samples.

How the data were processed

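The series profiled c-Jun binding by ChIP-seq in BT549, an established human triple-negative breast cancer cell line. In ChIP-seq, chromatin is crosslinked and fragmented, fragments bound by a protein are recovered with an antibody, and the recovered DNA is sequenced. Of the 4 libraries, 2 were made with an antibody against c-Jun, 1 with normal rabbit IgG and 1 from input chromatin. Per the labels, 1 c-Jun library came from cells that received TNFalpha and 1 from cells that did not, and the IgG and input libraries both came from TNFalpha-treated cells. The labels disagree on the length of the treatment: the sample labels give 6 hours and the series text gives 3 hours. Chromatin was fixed with 1% formaldehyde for 10 minutes, per the labels' protocols.

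Reads were base-called with CASAVA 1.8 and aligned with Bowtie 0.12.9 to hg19, per the submitters' processing notes. The deposited files were 4 peak lists without headers, 2 for each c-Jun library: 1 called against IgG and 1 called against input, per the labels and the file names. The peak names in the files begin with MACS, the name of a peak caller. Its version, its threshold, its handling of duplicate reads and any filter on problem regions are not given in the sources used here. Each deposited peak carried a score made by the authors' peak caller. The lowest score in each list was about 50, and the scale of the score is not given in the sources used here, so scores were used only to describe and rank peaks inside a list. Each list came from 1 ChIP library, with no pooling described in the labels. Read numbers were not used here, so the sequencing depth of each library is unknown. A deeper library gives more peaks at a fixed threshold, and a difference in peak number between the libraries therefore carries an unknown contribution of depth.

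The 2 lists of a library are 2 calls on the same c-Jun reads and are not replicates. Each condition had 1 library, so no difference between conditions could be set against a spread between replicates, and no p-value was computed. Start positions were raised by 1 from the BED convention, and all coordinates are 1-based positions on hg19.

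IgG-controlled peaks that overlapped an input-controlled peak of the same library by at least 1 bp were kept as both-control peaks. A both-control peak was called shared if it overlapped any peak of either list of the other library by at least 1 bp, and was otherwise assigned to its own library only. A peak was thus called present only against both controls and absent only against both. Shared peaks were counted in each library separately, so the numbers of the 2 libraries need not be equal. Shares are given with 95% Wilson confidence intervals, which treat peaks as independent and cover counting error only. For a share of 0, the limit given is 3 counts of the total. Overlap by chance was measured by placing the peaks 1000 times at random positions of their own chromosome, with the highest peak end in any list taken as the end of the chromosome. Distances to the other library were set against 100 such placements.

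The clustering of peaks found only with TNFalpha was described by counting successive both-control peaks with centres at most 100 kb apart that were both found only with TNFalpha. This count was set against 1000 shuffles of the class among peaks of the same score decile, and against 1000 shuffles within chromosome and score tercile. Regions were built by chaining both-control peaks at most 50 kb apart, and those with at least 4 peaks found only in 1 library were listed. Dense runs were chains of at least 10 input-controlled peaks with gaps of at most 10 kb. The clustering, regions, dense runs, distances to the other library and densities per chromosome were chosen after the peak lists had been examined. The classes, the overlap rule, the score deciles, the random placements and the alternatives in the closing section not marked as added were chosen before the data were examined.

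The peaks named in the text are the 10 with the highest score of each class, ranked in the IgG-controlled list of their library, or of the library with TNFalpha for shared peaks. This rule was also set before the data were examined. Regions and dense runs are named by the number of peaks they hold. Positions relative to genes, sequence motifs, gene lists and a set of individual genes had also been planned. These were not analysed here, because no genome or annotation of hg19 was used, and peaks are therefore named by coordinates alone.

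Overlaps and intervals were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. The overlap code was tested against bedtools 2.31.1 on the 12 ordered pairs of lists under 3 overlap rules, and 0 of 36 counts differed. On simulated libraries it recovered 800 of 800 peaks placed only in the library with TNFalpha and 300 of 300 placed only in the other. Each simulated peak was put in both lists of its library with no missed calls. This checks the code and not whether real peaks were missed. In simulated labellings for the neighbouring pairs, 19 of 20 random labellings fell inside the central 95% of shuffles, and a labelling laid down in blocks lay above every shuffle. Alternatives covered the control used, the overlap rule, the score, the number and the width of peaks, and the chromosomes included.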

Results

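Genome-wide c-Jun binding was mapped by ChIP-seq in serum-starved BT549 cells that were or were not exposed to TNFalpha, an inflammatory cytokine. c-Jun is a subunit of AP-1, a transcription factor that binds DNA as a dimer. The data were 4 peak lists from 2 c-Jun libraries, 1 per condition, each called against IgG and against input chromatin. Neither condition was replicated, so every difference below describes these 2 libraries and has no replicate check. The read depth of the libraries is unknown.

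Against IgG, 3323 c-Jun peaks were called without TNFalpha and 4439 with TNFalpha, a ratio of 1.34. The peaks covered 1422 kb without TNFalpha and 2107 kb with it, a ratio of 1.48. The median peak was 392 bp wide without TNFalpha (interquartile range 320 to 492 bp) and 427 bp wide with TNFalpha (349 to 546 bp). Against input, the lists were longer and nearly equal in number, with 7919 peaks without TNFalpha and 8040 with TNFalpha, a ratio of 1.02. These covered 2713 kb and 3247 kb, with median widths of 288 bp and 351.5 bp. The larger number of peaks with TNFalpha was therefore seen against IgG and was not seen to a similar extent against input.

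To find the peaks called against both controls, the IgG-controlled and input-controlled lists of each library were compared. Without TNFalpha, 3086 of 3323 IgG-controlled peaks were also called against input (92.9%, 95% Wilson interval 91.9 to 93.7%). With TNFalpha, 4159 of 4439 were (93.7%, 92.9 to 94.4%). In the other direction, 39.0% of the input-controlled peaks without TNFalpha were also called against IgG (37.9 to 40.0%), and 51.7% of those with TNFalpha were (50.6 to 52.8%). Random placement of the peaks on their own chromosomes gave a mean overlap of at most 0.26% in these comparisons. The 3086 and 4159 both-control peaks were used for the comparison of conditions.

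The main question of the design was which c-Jun sites differ between cells with and without TNFalpha. Of the 4159 both-control peaks with TNFalpha, 2666 overlapped a peak of the library without TNFalpha (64.1%, 95% Wilson interval 62.6 to 65.5%) and 1493 did not (35.9%, 34.5 to 37.4%). Of the 3086 both-control peaks without TNFalpha, 2466 overlapped a peak of the library with TNFalpha (79.9%, 78.5 to 81.3%) and 620 did not (20.1%, 18.7 to 21.5%). Peaks found only with TNFalpha outnumbered those found only without it by 2.41 to 1. The list with TNFalpha was also the longer, and with similar shared numbers a longer list leaves more peaks unmatched. The shares above count a hit in either list of the other library. When the other library's both-control peaks alone counted as hits, 49.5% of the peaks with TNFalpha and 66.9% of those without it were shared. Chance placement gave mean overlaps of 0.24% and 0.26%. The ratio differed between the sets of peaks compared. In the input-controlled lists alone, which are longer, 3951 peaks were found only with TNFalpha and 3783 only without it, a ratio of 1.04. Within the same lists the ratio was 1.39 among the higher scoring 50% of peaks and 5.06 among the highest scoring 10%. Among the input-controlled peaks not called against IgG the ratio was reversed. Here 2374 of 3881 peaks were found only with TNFalpha and 3114 of 4833 only without it, a ratio of 0.762. The list without TNFalpha was the longer in this set. When the same number of highest scoring IgG-controlled peaks, 3323, was taken from each library, the numbers were 1418 and 1402, a ratio of 1.01, as equal list lengths require the numbers to be nearly equal.

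**Figure D1:**
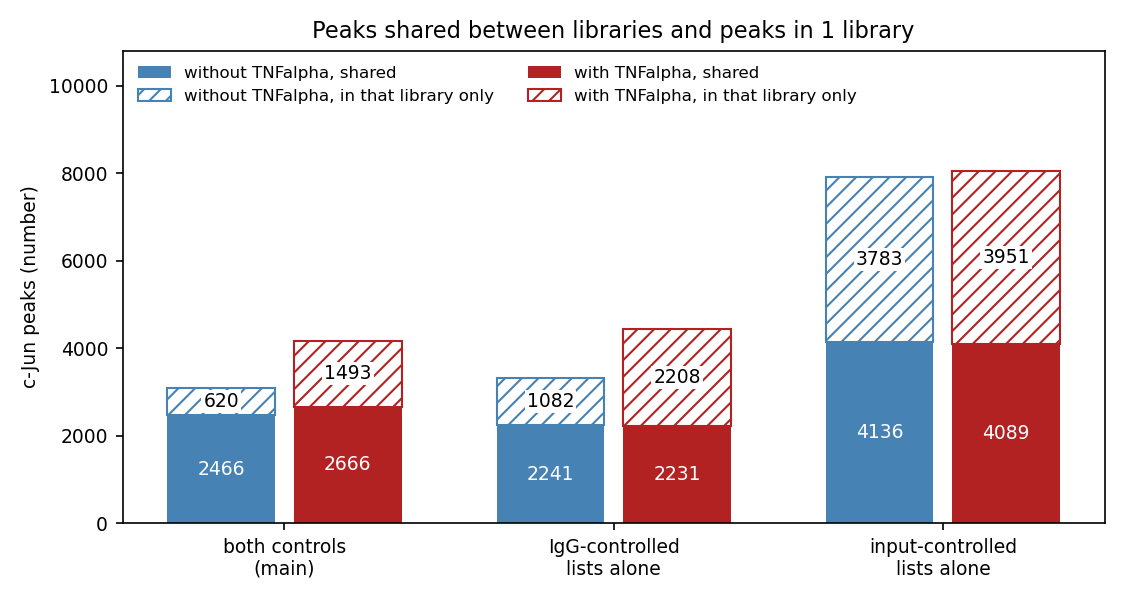
Numbers of c-Jun peaks (vertical axis) in the library without TNFalpha (blue) and with TNFalpha (red), split into peaks that overlap a peak of the other library (filled) and peaks in that library only (hatched), for both-control peaks, the IgG-controlled lists alone and the input-controlled lists alone. The hatched part is larger with TNFalpha for both-control peaks (1493 against 620) and for IgG-controlled peaks (2208 against 1082), and nearly equal for input-controlled peaks (3951 against 3783).

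Peaks found in 1 library were weaker and narrower than shared peaks of the same list. With TNFalpha, the median score was 74.9 for peaks found only in that library and 102.1 for shared peaks, and the median widths were 394 bp and 456 bp. Without TNFalpha, the median scores were 64.2 and 88.0, and the median widths were 337 bp and 412 bp. The share of peaks absent from the other library fell with the score in both libraries. In the lowest score decile it was 56.3% with TNFalpha (95% Wilson interval 51.4 to 60.9%) and 37.5% without TNFalpha (32.3 to 43.1%). In the highest decile, 49 of 415 peaks with TNFalpha were absent from the library without it (11.8%, 9.05 to 15.3%), against 3 of 308 in the opposite direction (0.974%, 0.332 to 2.82%). These intervals cover counting error within a library, the deciles come from lists of different length, and no difference between conditions was tested. Among the input-controlled peaks alone, the highest scoring 10% also held more peaks found only with TNFalpha (91 of 810) than only without it (18 of 792).

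**Figure D2:**
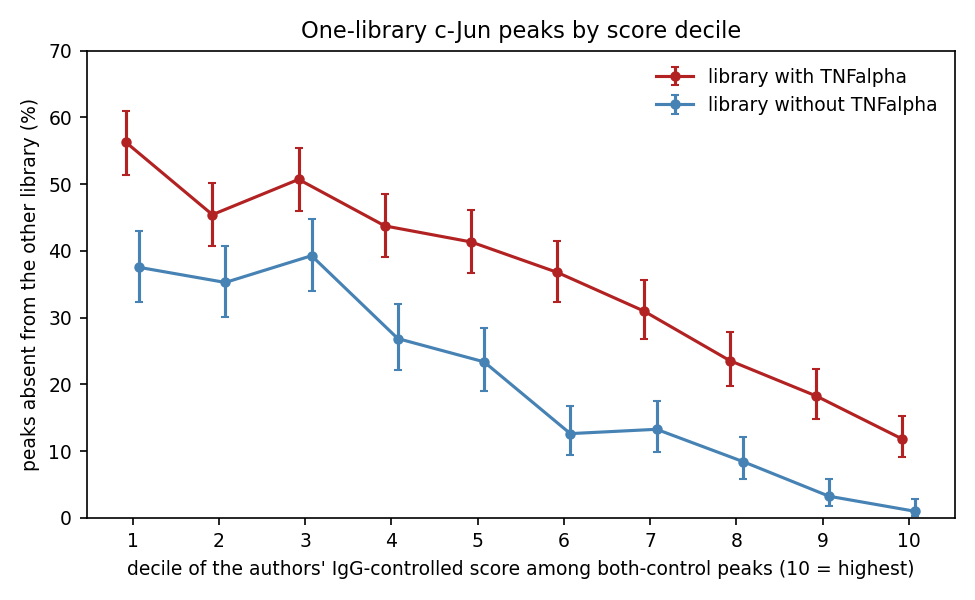
Percent of both-control c-Jun peaks absent from both lists of the other library (vertical axis) by decile of the authors' IgG-controlled score within the library (horizontal axis, 10 highest), for the libraries with TNFalpha (red) and without TNFalpha (blue). Points are percentages with 95% Wilson intervals. The percentage falls from 56.3% to 11.8% with TNFalpha and from 37.5% to 0.974% without it.

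The 10 highest scoring shared peaks also held ranks 1 to 10 among all 4159 both-control peaks with TNFalpha. Each was called in both lists of the library without TNFalpha, and they were 493 to 1388 bp wide. The highest lay on chromosome 6 from 135229688 to 135230782, with a score of 672.0 against IgG and 987 against input. It was followed by peaks on chromosome 10 from 37777874 to 37778995 (score 632), on chromosome 8 from 109131783 to 109133170 (score 612) and from 8394844 to 8395813 (score 596), and on chromosome 15 from 93346833 to 93347836 (score 559.9). The remaining shared peaks lay on chromosome 5 from 116102055 to 116102726, on chromosome 1 from 7461790 to 7462450 and from 36852060 to 36852552, on chromosome 10 from 33294166 to 33295085 and on chromosome 22 from 30591757 to 30593123, with scores from 532 to 555.

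Among peaks found only with TNFalpha, the highest scoring lay on chromosome 6 from 160137080 to 160138294, with a score of 468 against IgG and 658 against input. It ranked 21 among the 4159 both-control peaks with TNFalpha, and the nearest peak without TNFalpha was 14.0 kb away. The next lay on chromosome 22 from 30601285 to 30602226 (score 384), 8.29 kb from a peak present without TNFalpha. A peak on chromosome 6 from 89744966 to 89746060 (score 367) was 110 kb from any peak without TNFalpha, and a peak on chromosome 20 from 48428012 to 48429989 (score 304) was 290.2 kb away. The others were on chromosome 11 from 95888916 to 95889969 (score 346), chromosome 3 from 45592923 to 45593609 (score 335), chromosome 8 from 22249757 to 22251513 (score 289.8), chromosome 1 from 9747147 to 9747716 (score 286), chromosome 9 from 33159305 to 33160347 (score 279.7) and chromosome 14 from 101910353 to 101910904 (score 277). The peak on chromosome 9 lay 505 bp from a peak without TNFalpha.

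Among peaks found only without TNFalpha, the highest scoring lay on chromosome 10 from 78435281 to 78436407, with a score of 213 against IgG and a rank of 177 among the 3086 both-control peaks of its library. The nearest peak with TNFalpha was 487 kb away. The next lay on chromosome 8 from 91952565 to 91953695 (score 185), chromosome 5 from 151078657 to 151079126 (score 184) and chromosome 4 from 86953668 to 86954189 (score 159). The peak on chromosome 4 lay 81 bp from a peak with TNFalpha and counted as shared when peaks within 500 bp were joined. The remaining peaks had scores of 136 to 152 and lay on chromosome 7 from 100464696 to 100465116, on chromosome 3 from 188311946 to 188312396, from 15838989 to 15839834 and from 167532144 to 167532766, on chromosome 20 from 48077507 to 48077909 and on chromosome 12 from 66285863 to 66286294.

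Peaks found only with TNFalpha lay closer to peaks of the library without TNFalpha than the same peaks placed at random. They also neighboured each other more often than in shuffles of the class. Random placement used the whole chromosome, so it does not separate closeness to the other library from a general concentration of c-Jun peaks in parts of the genome. Both 1-library classes lay closer than on random placement. For peaks found only with TNFalpha, the median distance to the nearest peak of the library without TNFalpha was 37.7 kb. The same peaks placed at random had a median of 197 kb. Of the 1493 peaks, 547 lay within 20 kb (36.6%, 95% Wilson interval 34.2 to 39.1%), against 9.02% on random placement. Peaks found only without TNFalpha lay at a median of 51.4 kb from the nearest peak with TNFalpha, against 238 kb on random placement, and 200 of 620 were within 20 kb (32.3%, 28.7 to 36.0%), against 8.35% on random placement. When distances were taken to the other library's both-control peaks alone, 22.97% and 20.97% lay within 20 kb, against 3.95% and 4.97% on random placement. Successive peaks at most 100 kb apart were both found only with TNFalpha in 254 cases, more than in any of 1000 shuffles within score deciles (mean 191, highest 237). The corresponding count without TNFalpha was 38, inside the central 95% of shuffles (22 to 42). The counts were 1.33 times the shuffled mean with TNFalpha and 1.20 times without it. For peaks up to 500 kb apart, the ratios were 1.163 and 1.142 in shuffles within score deciles. In shuffles within chromosome and score tercile at this distance they were 1.158 and 1.169. The difference between the libraries in this clustering was not tested.

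Chaining both-control peaks at most 50 kb apart gave 15 regions with at least 4 peaks found only with TNFalpha, against a mean of 4.03 and a highest count of 11 in 1000 shuffles within score deciles. In the library without TNFalpha, 0 regions held 4 or more of its 620 peaks found only there, as was also the case in 966 of 1000 shuffles. The region with the most lay on chromosome 4 from 74545541 to 74606359 and held 7 peaks found only with TNFalpha and 3 shared peaks over 60.8 kb. Its shared peak with the highest score against IgG, from 74569948 to 74570951, had a score of 276 with TNFalpha. Of its peaks found only with TNFalpha, the one from 74591349 to 74592201 had the highest score against IgG (165) and a score of 442 against input. The peak from 74594922 to 74595529 had the highest score against input (447). The last of them, from 74606108 to 74606359, had a score of 50.8 against IgG, close to the lowest score in that list. A region on chromosome 10 from 14020364 to 14052611 held 5 peaks found only with TNFalpha and 0 shared peaks. Another on chromosome 10, from 3825080 to 3929511, held 5 and 3. Regions with 4 peaks found only with TNFalpha and 0 shared peaks lay on chromosome 11 from 61739058 to 61793292, on chromosome 6 from 16684011 to 16725783 and from 137540335 to 137561849, and on chromosome 9 from 4166965 to 4236550.

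**Figure D3:**
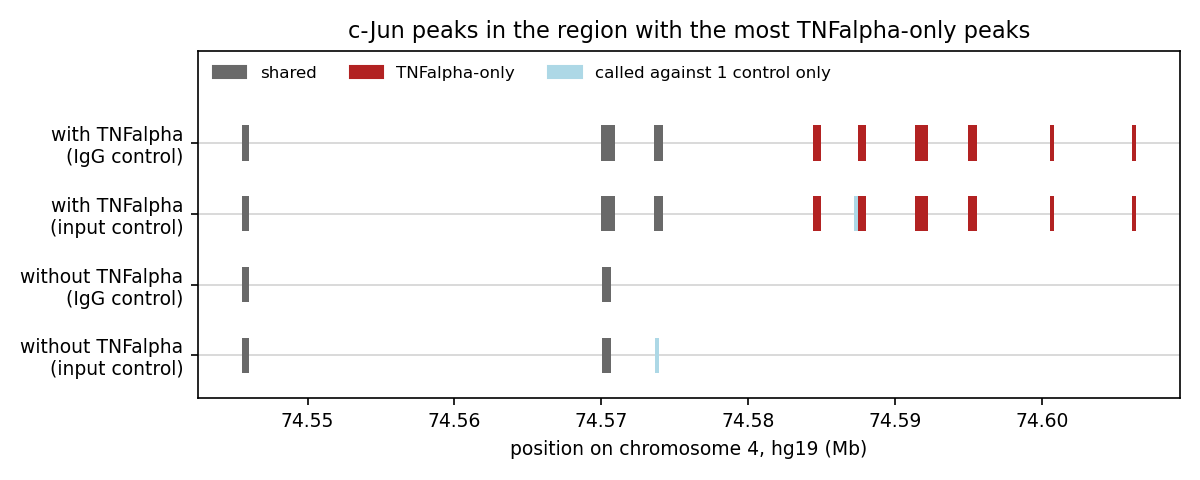
Positions of c-Jun peaks on chromosome 4 (horizontal axis, hg19, in Mb) in each of the 4 peak lists (rows), drawn to scale and coloured by class, in the region with the most peaks found only with TNFalpha. The 3 shared peaks lie at lower coordinates than the 7 peaks found only with TNFalpha, of which 2 adjacent peaks near 74587435 are drawn almost touching. The peak near 74573618 was called without TNFalpha against input only.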

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

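No paired analysis was possible because each condition had 1 library, and for the same reason no library could be left out. Read depth, which limits any statement that a site is absent, is unknown. Numbers are given for peaks found only with TNFalpha, peaks found only without it, and shared percentages with and without TNFalpha, in that order. The main values were 1493, 620, 64.1% and 79.9%. With the IgG-controlled lists alone they were 2208, 1082, 50.3% and 67.4%. With the input-controlled lists alone they were 3951, 3783, 50.9% and 52.2%, and the ratio of the first 2 fell from 2.41 to 1.04. Against the other library's both-control peaks alone they were 2100, 1020, 49.5% and 66.9%. With reciprocal overlap of at least 50% of both peaks they were 1779, 794, 57.2% and 74.3%. Counting peaks within 500 bp as shared raised the percentage with TNFalpha to 66.3%. Among both-control peaks in the higher scoring 50% of the IgG-controlled lists they were 556, 142, 74.8% and 91.4% (ratio 3.92). Among those in the highest scoring 10% of these lists, 445 and 333 peaks, they were 54, 3, 87.9% and 99.1% (ratio 18). The highest deciles of both-control peaks above, with 415 and 308 peaks, are different sets. With equal numbers of IgG-controlled peaks they were 1418, 1402, 57.3% and 57.8% (ratio 1.01), which equal list lengths produce by construction. Overlap of at least 50% of the shorter peak and restriction to chromosomes 1 to 22 and X changed no value beyond its interval, and no both-control peak was over 5 kb wide.

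Further alternatives were added after seeing the data. In the input-controlled lists alone, the higher scoring 50% gave 1225, 879, 69.6% and 77.8% (ratio 1.39), and the highest scoring 10% gave 91, 18, 88.8% and 97.7% (ratio 5.06). Input-controlled peaks not called against IgG gave 2374, 3114, 38.8% and 35.6%, and here the ratio reversed to 0.762. These sets held 3881 peaks with TNFalpha and 4833 without it, and the longer list favours a ratio below 1. No other cause was tested. Without the dense runs, the input-controlled lists gave 3894, 3627, 48.5% and 50.5% (ratio 1.07), and the input-controlled peaks not called against IgG gave 2317, 2958, 31.8% and 30.2%, with the ratio still reversed (0.783). No both-control peak lay in a dense run, so their removal could not change the main values.

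Among the higher scoring 50% of each list, 99.1% of IgG-controlled peaks without TNFalpha and 99.3% with it were also called against input, and 66.2% and 79.0% of input-controlled peaks were also called against IgG. Keeping scores at or above the median left 1668 and 2220 IgG-controlled and 3960 and 4024 input-controlled peaks without and with TNFalpha, as the filter requires. The clustering ratio of 1.33 and its alternatives were also chosen after seeing the data. It was 1.496 for neighbours up to 20 kb apart, 1.16 up to 500 kb, and 1.33 with peaks within 5 kb joined. For the library without TNFalpha the ratio was 1.20 up to 100 kb, 1.17 up to 20 kb and 1.14 up to 500 kb. The intended comparisons of gene positions, motifs and gene lists were not run. When peaks within 500 bp counted as shared, 10 of the 10 named peaks found only with TNFalpha and 9 of the 10 found only without it stayed in their class. In other alternatives some named peaks were no longer among the peaks compared. The highest scoring 10% kept 10 and 3, the highest scoring 10% of the input-controlled lists kept 8 and 5, and input-controlled peaks not called against IgG kept 0 and 0, as both-control peaks are excluded there.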

Other observations

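The density of both-control peaks with TNFalpha differed between chromosomes by up to 3.78 times. With TNFalpha, both-control peaks were densest on chromosome 8 (2.40 per Mb), chromosome 20 (2.38 per Mb) and chromosome 5 (2.05 per Mb). They were sparsest on chromosome X (0.634 per Mb), chromosome 16 (0.732 per Mb) and chromosome 11 (0.759 per Mb), with a median of 1.04 per Mb over 23 chromosomes. Without TNFalpha, chromosomes 8 (1.87 per Mb) and 20 (1.81 per Mb) were again the densest. The sparsest without TNFalpha were chromosomes 22 (0.357 per Mb), 21 (0.400 per Mb) and X (0.485 per Mb). On each of the 23 chromosomes, peaks found only with TNFalpha outnumbered those found only without it. Each chromosome also held more both-control peaks with TNFalpha than without it, which favours this outcome, so it is not separate support for an effect of TNFalpha. Peaks found only with TNFalpha made up 65.1% of the 43 peaks on chromosome 22 (95% Wilson interval 50.2 to 77.6%), the highest share. On chromosome 4 they made up 29.2% of the 195 peaks (23.3 to 36.0%), the lowest share. Chromosome 22 also had the highest share of peaks found only without TNFalpha (33.3% of 18 peaks, 16.3 to 56.3%). The copy number of the chromosomes was not measured here.

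The tests of clustering and of joined peaks in the next paragraph had their expectations set before their results were seen, while the test of dense runs was chosen after the runs had been seen.

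Peaks found only with TNFalpha outnumbered those found only without it among both-control peaks (1493 against 620). If the library without TNFalpha had only a lower sensitivity, alike at every site of a given score, the extra peaks would lie at random among peaks of the same score. The count of 254 neighbouring pairs was above the highest of 1000 shuffles within score deciles (237). This argues against a loss that depends on the score decile alone. Scores still differed inside a decile, from 200 to 672 in the highest with TNFalpha. The shuffles therefore cannot exclude a loss of sensitivity that follows the score more finely or varies between sites of the same score. Shuffles within chromosome and score tercile, a coarser control of the score, reached at most 229 pairs. The count was 1.31 times their mean, which argues against a difference acting on whole chromosomes as the only source of the clustering. These shuffles keep the class numbers of each chromosome, so they cannot decide whether such a difference contributed to the larger number of peaks. Joining peaks within 5 kb left 149 pairs against a highest shuffle of 139. This argues against wide sites called as several peaks as the only source of the clustering. A TNFalpha effect on binding at groups of neighbouring sites is a hypothesis that the clustering with TNFalpha allows, but no test here decides it. The difference in clustering between the libraries was not tested. Replicate libraries at matched depth and controls from untreated cells would be needed. A depth difference between the libraries and the TNFalpha-treated controls remain open as sources of the larger number of peaks found only with TNFalpha.

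Part of the input-controlled lists was packed into dense runs, 20 runs with 449 peaks with TNFalpha and 21 runs with 585 peaks without TNFalpha, among them 54 and 65 peaks on about 80.1 kb of an unplaced contig, and 50 and 64 peaks on chromosome 4 between 49093222 and 49158645 (bounds with TNFalpha). Of the peaks in these runs, 0% overlapped an IgG-controlled peak of the same library (0 of 449, which allows up to 0.668%, and 0 of 585, which allows up to 0.513%), against 54.8% and 42.1% of input-controlled peaks elsewhere. Of the dense-run peaks, 88.6% with TNFalpha and 74.0% without recurred in the other library, against 49.8% and 51.2% of input-controlled peaks elsewhere, but both libraries were called against the same input, so recurrence does not tell a signal in the c-Jun libraries from a low yield in the input. The absence of IgG-controlled peaks is consistent with signal that does not need the c-Jun antibody and is also in the IgG library. A lower yield of these regions in the input library alone was not tested, and no biological explanation was tested.

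The strongest scores against input also depended on the control. Of the 10 highest scoring input-controlled peaks, 5 with TNFalpha and 9 without TNFalpha had no overlapping IgG-controlled peak in their library. Chromosome Y held 149 input-controlled peaks with TNFalpha and 180 without, against 2 and 0 IgG-controlled peaks. This is not separate from the dense runs described above, as several of them lay on chromosome Y. The largest of these held 46 input-controlled peaks with TNFalpha and 61 without.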
